A study of Homo sapiens with 2 samples.

How the data were processed

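Gene expression was measured by RNA sequencing in 2 libraries of C4-2B ENZR cells, an established human prostate cancer line that resists the androgen receptor antagonist enzalutamide and was kept in 20 µM of it. The control library came from cells that carried a non-targeting short hairpin RNA, and the knockdown library came from cells that carried a hairpin against the coding sequence of NRP2. Each group holds 1 library, so no spread between replicates exists, no p-value between conditions is given, and every difference describes these 2 libraries with no replicate check. Neither the number of cultures behind a library nor their density or passage is given in the sources used here.

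The deposited values are a signal per gene symbol that the authors scaled by the TMM method to counts per unit of library size (CPM), per the labels of the deposited tables. Per the submitters' processing notes, the tools were bcl2fastq 2.17, Bowtie2 2.1.0, RSEM 1.2.15 and edgeR, with the genome build hg19. The role of each tool, the annotation, any read filter and the strand setting are not given in the sources used here. Both tables list 26475 symbols. Within each library all deposited values are whole multiples of the value of 1 read, 0.0487 in the control library and 0.0472 in the knockdown library, within a tolerance of 0.01 read for 100% of the values. Whole reads per gene were therefore recovered, 21052178 in the control library and 22992304 in the knockdown library. The columns sum to 1024943 and 1084413, more than CPM without TMM scaling would. If TMM scaling alone made these sums, they imply TMM factors of 0.976 and 0.922, both below 1. TMM factors that edgeR computes for a set of libraries multiply to 1, and these 2 do not; why is not given in the sources used here. The design fixed before the data were examined had assumed values in CPM; the values were used as deposited and are called CPM here.

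The change of a gene was taken as log2((knockdown CPM + 1)/(control CPM + 1)). This scale understates the change of genes with low values. Folds given beside it are plain ratios of CPM, with exact conditional binomial (Clopper-Pearson) 95% intervals from the recovered reads. Those intervals, and limits computed from 3 reads where a library had 0, cover counting error only, since reads without molecular identifiers are not independent molecules and cultures were not repeated. Genes with a mean of at least 1 CPM over both libraries were compared, 13316 in all, and a gene was counted as higher or lower at 2-fold on the log2(CPM + 1) scale. Another 28 symbols had been turned into calendar dates and name no gene; they held 0.181% and 0.184% of the reads of the control and the knockdown library and were left out.

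There were 40 gene lists, fixed before the data were examined, which covered lineage, signalling, stress, metabolism, cell cycle and markers of other cell types. A member was counted as higher or lower at 1.5-fold on the same scale. The median change of each list with at least 5 measured members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, and a list was said to stand apart within the lowest or the highest 2.5% of them. Of 37 lists placed, random draws of genes would put 1.85 there. Members were matched by symbol, 6 of them through an older or newer symbol. The 13 genes of the mitochondrial genome were not found under the symbols used and are not analysed here.

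Genes named in the text follow a rule fixed in advance: NRP2; the 15 largest and 15 smallest changes among genes with a mean of at least 5 CPM, leaving out sex-linked transcripts and models named as clones, pseudogenes, small RNAs or antisense transcripts; up to 4 members of each list with the largest change; and a fixed set of neuroendocrine, androgen receptor, neuropilin, lineage and proliferation genes. Some genes that the rule names are not reported here. A gene named outside this rule is marked as chosen after its value was seen. Reads of near-identical genes, readthrough models and overlapping transcripts cannot be told apart in these tables, so such genes are given as uncertain.

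Alternatives were pseudocounts of 0.25 and 5 CPM, no filter and a filter at a mean of 5 CPM, equal library totals, a median log2 ratio of 0, quantile normalization, a 1.5-fold threshold, counting intervals that exclude no difference, unmatched random lists, list means and lists without shared members. Chosen after seeing the data were an exact conditional binomial test on recovered reads with Benjamini-Hochberg adjustment, the removal of pseudogene, readthrough, antisense and uncharacterized models, the removal of a trend with GC content and transcript length, and androgen receptor targets without KLK2, KLK3, KLK4 and NDRG1. For that trend, properties of protein-coding transcripts in the GENCODE annotation of another build were matched by symbol, for 89.9% of the compared genes, and no coordinate was used. Calculations were done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots with matplotlib 3.10.9.

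The 2-fold rule was tested on simulated reads with the depths and levels of these libraries. They held counting error alone, with no difference between cultures, and the changed genes had means of at least 5 CPM. The 2-fold rule called 0% of genes simulated at 1.5-fold and 100% of those at 3-fold, 4-fold and 8-fold, 50 genes each, and 0% of unchanged genes. The last value does not tell how often cultures alone would differ 2-fold. The list placement was tested on the observed changes shuffled among genes, not on simulated reads. Of lists of 30 genes drawn at random, 5% stood apart, which shuffling nearly fixes in advance. Of 20 lists of 30 genes raised by 0.4 on the log2 scale, 100% did. Smaller shifts and lists of other sizes were not tried, so this does not tell how those would be placed.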

Results

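RNA sequencing compared C4-2B ENZR prostate cancer cells that carried a hairpin against NRP2 with cells that carried a non-targeting hairpin, 1 library each. NRP2 encodes neuropilin-2, a cell surface co-receptor for semaphorins and VEGF family ligands. The series is about NRP2 in the development of neuroendocrine prostate cancer, a form in which tumour cells lose androgen receptor signalling and gain neuroendocrine markers. The comparison asks which genes differed when NRP2 was targeted in cells that grow in enzalutamide. The control library held 21052178 reads on genes and the knockdown library 22992304, with 17174 and 17324 genes above 0. The 10 most abundant genes took 4.24% and 4.57% of the reads.

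NRP2, the targeted gene, was at 0.974 CPM in the control library and 0.330 CPM in the knockdown library. These levels rest on 20 and 7 reads. The ratio was 2.95-fold lower in the knockdown library, and the log2 change was -0.57, with a counting interval from -0.93 to -0.10. NRP2 was thus low in the control library too and lay under the mean of 1 CPM that other genes needed to be compared. Of the 500 genes nearest in level, 28 were as low or lower in the knockdown library relative to the control. The paralog NRP1, also a co-receptor for semaphorins and VEGF, had far more reads and was at 76.7 CPM in the control and 31.0 CPM in the knockdown, 2.48-fold lower (2.26 to 2.72).

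Across the transcriptome, more genes were higher than lower in the knockdown library. Of 13316 genes compared, 194 were at least 2-fold higher and 70 at least 2-fold lower, and 98.0% lay between. Genes induced by low oxygen, kallikreins and the protease inhibitor SLPI were among the largest increases. The single genes TNC, WNT5A, JAG1 and LEF1, of the extracellular matrix and of Wnt and Notch signalling, were among the largest decreases. As lists, Notch genes stood at percentile 99.7 of random lists and integrins, laminins and collagens at 99.5, both high, and Wnt genes at 25.4. The share of higher genes was 73.5% and depended on scaling: with both libraries set to equal totals, 137 genes were higher and 79 lower, a share of 63.4%. The median log2 change was 0.03 over all compared genes, and the central 95% of genes lay between -0.66 and 0.84. Log2(CPM + 1) correlated between the libraries across genes, which are not independent replicates, with Pearson r = 0.983. An exact conditional binomial test on the recovered reads called 6954 genes different at a Benjamini-Hochberg adjusted p under 0.05, including all 194 and 70. It compares these 2 libraries, not the conditions.

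PLOD2, a collagen lysyl hydroxylase, had the largest log2 change of the named genes, 3.65, with 1.22 CPM in the control and 26.8 CPM in the knockdown. CA9, a membrane carbonic anhydrase induced by hypoxia, was at 1.36 and 19.2 CPM (log2 3.10). C2orf54 was at 3.60 and 35.9 CPM. SLPI, a secreted inhibitor of leukocyte proteases, was at 34.8 and 230 CPM, 6.63-fold higher (6.13 to 7.18). The prostate kallikreins KLK3, which encodes prostate-specific antigen, and KLK2 had log2 changes of 2.67 and 2.43. PLA2G4D, a cytosolic phospholipase, was at 5.11 and 35.1 CPM. NDRG1, which responds to androgen and to hypoxia, was at 43.3 and 218 CPM. SLC16A3, the lactate exporter MCT4, was at 24.2 and 124 CPM, and PGF, placental growth factor, at 1.90 and 11.2 CPM. BNIP3, a mitochondrial mitophagy receptor, was at 149 and 622 CPM. The sphingosine-1-phosphate receptor S1PR3, the cation channel TRPM8 and the glycolysis regulator PFKFB4 followed, at log2 changes of 1.91, 1.85 and 1.83. RGPD5 was listed at 2.68 and 11.9 CPM, but its near-identical copies share reads, and RGPD6, chosen after its value was seen, was at 4.43 and 0 CPM, and the 7 listed RGPD genes together were at 74.2 and 67.0 CPM, so the increase of RGPD5 is uncertain.

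Among genes lower in the knockdown library, the matrix glycoprotein TNC was at 22.8 CPM in the control and 4.43 CPM in the knockdown, 5.14-fold lower (4.11 to 6.48). WNT5A, a ligand of non-canonical Wnt signalling, was at 83.8 and 19.2 CPM, 4.38-fold lower (3.92 to 4.89). OPRK1, the kappa opioid receptor, was at 34.2 and 7.97 CPM. The metalloprotease LMLN was at 30.2 and 8.58 CPM, and the chemokine CCL20 at 26.5 and 7.88 CPM. SLC22A3, an organic cation transporter, was at 117 and 38.1 CPM. The Notch ligand JAG1 was at 43.7 and 15.5 CPM, and LEF1, a transcription factor of the Wnt pathway, at 57.9 and 21.0 CPM. FAM198B, VAC14, the cytokine TNFSF15 and the endothelial lipase LIPG had log2 changes of -1.44, -1.41, -1.34 and -1.30. PPAN-P2RY11 and TEN1-CDK3 are readthrough models that overlap their parent genes, so their values are uncertain. The former had 225 reads in the control and 0 in the knockdown, while its parents PPAN and P2RY11, chosen after their values were seen, stood at 80.0 and 80.8 CPM and at 8.03 and 7.78 CPM. The latter was at 8.28 and 1.89 CPM.

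**Figure D1:**
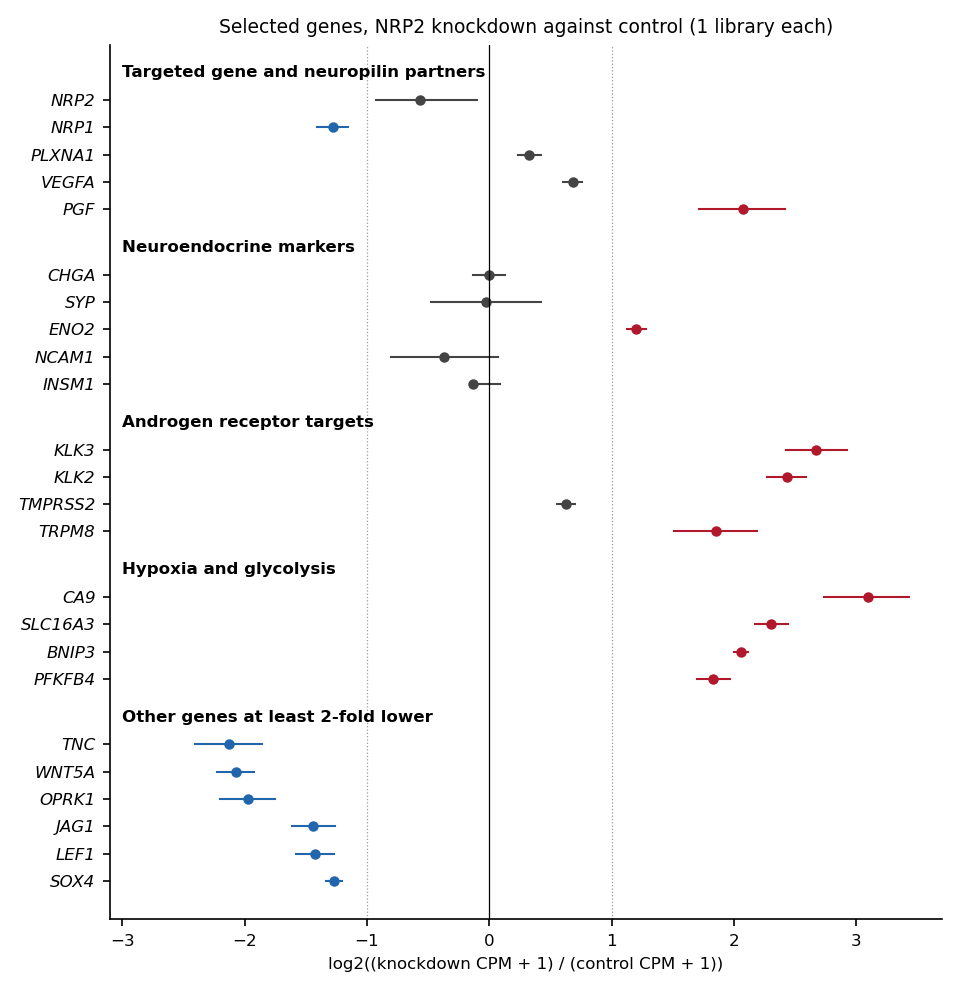
Log2((knockdown CPM + 1)/(control CPM + 1)) of selected named genes, on the horizontal axis, with 1 library per group; bars are 95% counting intervals and dotted lines mark 2-fold. Red points are at least 2-fold higher, such as CA9 at 3.10, blue points at least 2-fold lower, such as TNC at -2.13, and dark points lie between, such as NRP2 at -0.57.

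The neuroendocrine markers CHGA, INSM1, SYP and NCAM1 had few reads in both libraries. Chromogranin A (CHGA) had 1 read in each library, the transcription factor INSM1 had 2 reads in the control and 0 in the knockdown, and synaptophysin (SYP) had 31 reads in each. The adhesion molecule NCAM1 was at 2.19 and 1.46 CPM, a log2 change of -0.37 whose counting interval included no difference. ENO2, neuron-specific enolase and also a glycolytic enzyme, was at 91.3 CPM in the control and 211 CPM in the knockdown, 2.31-fold higher (2.19 to 2.44). Of 31 markers fixed, 11 had a mean of at least 1 CPM; ENO2 was the only member at least 1.5-fold higher and the neuropeptide NTS, at 4.92 and 2.78 CPM, the only member at least 1.5-fold lower. CELF3 was at 2.87 and 2.12 CPM. The median log2 change was -0.03, at percentile 25.9 of random lists, and turned to 0.27, at percentile 97.8, when only the 5 members with a mean of at least 5 CPM were kept.

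Neural lineage and plasticity regulators went both ways. SOX4, a transcription factor tied to progenitor states, was at 314 CPM in the control and 130 CPM in the knockdown, 2.42-fold lower (2.31 to 2.53), and SOX9 was at 26.6 and 14.0 CPM. PEG10, an imprinted gene derived from a retrotransposon, was at 4.28 and 7.64 CPM, and LHX2 at 3.07 and 4.86 CPM. Of 13 measured regulators, 1 was at least 1.5-fold higher and 2 lower, and the median of 0.13 stood at percentile 82.1. POU3F2, the neural factor BRN2, had 15 and 6 reads, a difference within counting error (ratio 2.58-fold lower, 0.946 to 8.12). MYCN had 0 and 2 reads, SOX2 had 0 and 1, and FOXA2 had 0 in both, which allows up to 0.146 and 0.141 CPM. EZH2 was at 52.8 and 57.4 CPM, and AURKA at 92.1 and 79.1 CPM. Polycomb and other chromatin repressors did not stand apart (33 measured, median 0.04, percentile 43.5). Their largest change was that of the REST corepressor RCOR2, at 3.60 and 8.63 CPM.

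Androgen receptor targets stood apart on the high side, led by the kallikreins. KLK3 was at 5.60 CPM in the control and 41.0 CPM in the knockdown, 7.33-fold higher (6.03 to 8.98), and KLK2 was at 16.4 and 92.5 CPM, 5.65-fold higher (5.03 to 6.37). TRPM8 was 4.71-fold higher (3.45 to 6.54). TMPRSS2, an androgen-induced serine protease, was at 117 and 181 CPM. The pioneer factor FOXA1 was at 453 and 302 CPM. Of 30 measured targets, 9 were at least 1.5-fold higher and 0 lower, and the median of 0.15 stood at percentile 98.5. Without KLK2, KLK3, KLK4 and NDRG1, a set chosen after KLK2, KLK3 and NDRG1 had been seen to be high, the median was 0.12, at percentile 90.9; taking out high members lowers any list, and 5 of the 26 members left were at least 1.5-fold higher and 0 lower. The whole list no longer stood apart without a filter on low values (percentile 94.6) or under quantile normalization (percentile 95.3). Genes of steroid metabolism did not stand apart (14 measured, percentile 70.7, 0 higher and 2 lower). The 2 lower members were UGT2B11 (6.77 and 3.82 CPM) and UGT2B17 (log2 change -0.61), and their relative UGT2B15 was at 23.9 and 15.6 CPM, though this family shares reads. AKR1C2 was at 1.17 and 1.98 CPM.

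Luminal, basal, mesenchymal and stem cell lists did not stand apart. Among 29 luminal markers (median 0.15, percentile 96.9), KRT19 was at 10.9 and 26.0 CPM, the tight junction genes CLDN4 at 192 and 337 CPM and CLDN3 at 37.2 and 58.8 CPM, and RAB25 was lower, at 68.5 and 32.4 CPM. E-cadherin (CDH1) was at 529 and 788 CPM. Of 10 basal markers (percentile 54.5), the growth factor receptor EGFR was at 31.3 and 97.8 CPM, 3.13-fold higher (2.86 to 3.42), CAV1 at 1.46 and 2.88 CPM, ITGB4 at 29.8 and 21.4 CPM and LAMB3 at 5.99 and 7.78 CPM. Of 14 mesenchymal markers (median 0.18, percentile 94.1), fibronectin (FN1) was at 498 and 1541 CPM, 3.10-fold higher (3.03 to 3.17), thrombospondin-1 (THBS1) at 24.6 and 67.1 CPM, TGM2 at 0.535 and 3.11 CPM, and vimentin (VIM) at 39.4 and 58.8 CPM, while WNT5A was lower. Of 13 stem cell genes (percentile 49.7), POU5F1 was at 2.68 and 4.72 CPM, MSI1 at 18.2 and 23.6 CPM, ABCG2 at 2.82 and 3.73 CPM and CD9 at 343 and 417 CPM.

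VEGF and semaphorin ligands and receptors, the binding partners of neuropilins and their relatives, stood apart on the high side. PGF was 5.89-fold higher (4.18 to 8.49), the semaphorin SEMA6B was at 3.94 and 12.7 CPM, VEGFB at 3.02 and 9.86 CPM and VEGFA at 98.8 and 159 CPM. Of 28 measured members, 8 were at least 1.5-fold higher and 4 lower, NRP1 among the latter, and the median of 0.29 stood at percentile 99.99. PLXNA1, a plexin that signals with neuropilins, was at 73.1 and 92.0 CPM, and VEGFC, a lymphatic growth factor that binds NRP2, had 0 reads in both libraries. Integrins, laminins and collagens were also placed high (19 measured, median 0.25, percentile 99.5, 3 higher and 0 lower), with ITGA11 at 0.535 and 2.08 CPM, COL4A6 at 1.22 and 3.21 CPM, ITGB2 at 1.22 and 2.36 CPM and LAMB2 at 121 and 157 CPM, but its mean change stood at 96.4. Other axon guidance genes did not stand apart (24 measured, median 0.15, percentile 96.7): EFNA2 was at 1.17 and 3.44 CPM, L1CAM at 1.27 and 3.63 CPM, EPHA3 at 20.7 and 36.4 CPM and EPHB6 at 2.29 and 0.849 CPM.

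Hypoxia and glycolysis genes had the highest median of all 37 lists placed. CA9, SLC16A3, BNIP3 and PFKFB4 were 14.1-fold, 5.10-fold, 4.18-fold and 3.66-fold higher in the knockdown library, each with a counting interval above 3. Of 31 measured members, 19 were at least 1.5-fold higher, 13 of them at least 2-fold, and 0 lower. The median log2 change was 0.72, and 0 of 10000 random lists had a median as high. Genes of transcription factors of the response to low oxygen, chosen after the list's value was seen, were nearly level in RNA. HIF1A was at 111 and 125 CPM, 1.13-fold higher (1.06 to 1.19), EPAS1 at 6.91 and 6.93 CPM and ARNT at 73.2 and 75.2 CPM. RNA levels do not measure the activity of these factors, which was not tested.

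**Figure D2:**
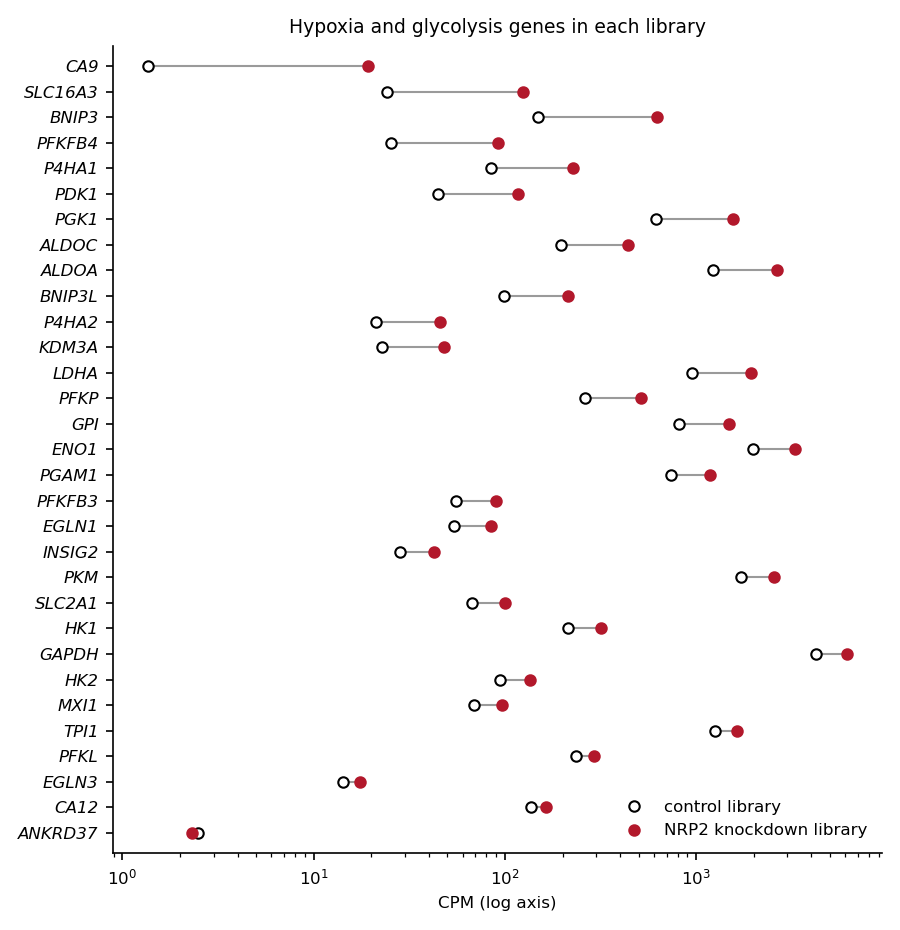
Level in CPM (log axis) of the 31 measured hypoxia and glycolysis genes in the control library (open circles) and the NRP2 knockdown library (red circles), 1 library each, ordered by log2 change. All but the lowest gene of the plot were higher in the knockdown library, with CA9 showing the widest gap.

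Mitotic genes were slightly lower as a group, while S phase genes were level. CCNB1, the mitotic cyclin B1, was at 194 CPM in the control and 134 CPM in the knockdown, KIF4A at 81.9 and 58.8 CPM and CENPE at 49.6 and 37.6 CPM, whereas CDK1 was at 350 and 463 CPM and MKI67 at 206 and 240 CPM. None of 40 mitotic genes passed 1.5-fold; 28 lay below 0 and 12 above, and the median of -0.10 stood at percentile 0.04. The 40 S phase genes had a median of 0.05 at percentile 52.7, with WDR76 at 45.6 and 63.6 CPM, CCNE2 at 48.8 and 64.0 CPM, BLM at 20.6 and 16.2 CPM and PRIM1 at 49.5 and 61.3 CPM. Homologous recombination and DNA repair genes stood at percentile 8.78 (33 measured), with BRCA2 at 55.6 and 42.2 CPM, ATM at 31.4 and 24.0 CPM and PALB2 at 26.6 and 21.0 CPM. Replication-dependent histones (12 measured) stood at percentile 66.6.

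Antigen presentation genes were higher in the knockdown library. The class I genes HLA-B and HLA-E were at 69.6 and 127 CPM and at 45.5 and 79.0 CPM, the class II chaperone gene HLA-DMB at 4.82 and 9.81 CPM, and the immunoproteasome subunit PSMB9 at 3.51 and 6.46 CPM. Of 20 measured members, 7 were at least 1.5-fold higher and 0 lower, and 0 of 10000 random lists reached the median of 0.49. HLA genes share reads with one another. Type I interferon response genes did not stand apart (27 measured, median 0.14, percentile 96.0, 5 higher and 0 lower), though 4 alternatives placed them apart on the high side and the removal of a GC and length trend put them at percentile 89.1; SAMD9 was at 2.82 and 7.64 CPM, IFI6 at 33.6 and 62.8 CPM, OAS1 at 2.39 and 4.86 CPM and IFI35 at 15.5 and 24.1 CPM. NF-kB and inflammatory genes stood at percentile 17.6 (14 measured, 2 higher and 1 lower), with CCL20 lower, IL32 (5.16 and 8.54 CPM) and ICAM1 (29.6 and 45.4 CPM) higher and BIRC3 at 12.9 and 8.87 CPM.

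**Figure D3:**
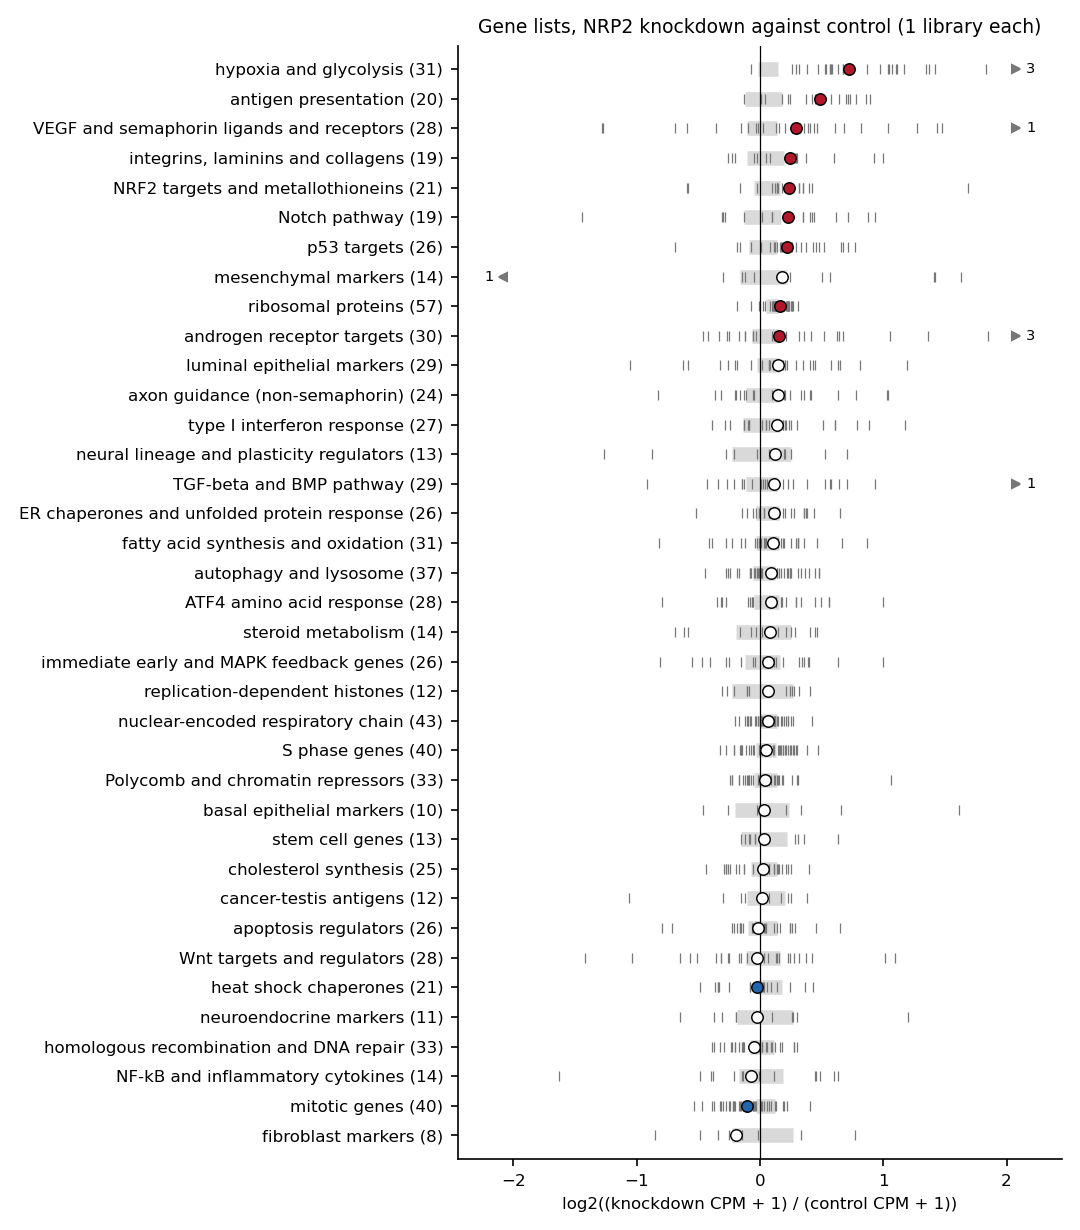
Median log2((knockdown CPM + 1)/(control CPM + 1)) of 37 gene lists (circles, number of measured genes in brackets), with single members as ticks, members beyond 2 in size counted at the edge, and grey bars for the central 95% of 10000 random lists matched on expression. Red circles mark the 9 lists that stood apart on the high side, hypoxia and glycolysis at 0.72 the furthest, and blue circles the 2 on the low side.

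In all, 11 of the 37 lists placed stood apart, 9 high and 2 low, where random draws of genes would give 1.85. That number does not allow for members of a list that vary together between the libraries, for any reason. p53 targets (26 measured, median 0.22, percentile 99.96, 4 higher and 1 lower) included ZMAT3 at 32.2 and 55.6 CPM, the death receptor FAS at 7.35 and 12.7 CPM, SPATA18 at 5.40 and 9.24 CPM and, in the other direction, PLK2 at 15.9 and 9.48 CPM. NRF2 targets and metallothioneins (21 measured, median 0.23, percentile 99.95) had 1 higher member, heme oxygenase HMOX1, at 18.7 and 62.4 CPM, and 1 lower, PGD at 307 and 204 CPM, with OSGIN1 at 18.1 and 11.8 CPM and GCLC at 27.8 and 37.6 CPM. Notch pathway genes (19 measured, median 0.23, percentile 99.7, 4 higher and 1 lower) had the receptor NOTCH3 at 184 and 351 CPM, HES2 at 3.46 and 7.17 CPM and the ligand DLL1 at 4.58 and 8.16 CPM, against JAG1; the list's mean stood at 95.3, and its median at 90.7 without a filter. Ribosomal protein genes (57 measured, median 0.16, percentile 99.1) moved little, none past 1.5-fold, with RPL18 at 563 and 699 CPM, RPS28 at 618 and 745 CPM and RPL3 at 3168 and 3786 CPM, and under quantile normalization their median was -0.00 at percentile 55.8. Heat shock chaperones (21 measured, median -0.03, percentile 1.92) had no member past 1.5-fold, with HSPA8 at 3189 and 2475 CPM, HSPB1 at 725 and 978 CPM, BAG3 at 78.4 and 101 CPM and HSPA1B, which shares reads with its copy, at 717 and 512 CPM; their position was 23.2 against unmatched random lists.

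Signalling lists that did not stand apart held some large single changes. Of 28 Wnt genes (percentile 25.4), LEF1 and TNFRSF19 (152 and 73.6 CPM) were lower and the Wnt deacylase NOTUM (0.682 and 2.59 CPM) and TCF7L1 (0.828 and 2.69 CPM) higher. Of 29 TGF-beta and BMP genes (percentile 93.7), TGFB1 was at 0.876 and 8.68 CPM, 9.90-fold higher (6.09 to 17.1), INHBE at 0.682 and 2.22 CPM, SMAD9 at 6.62 and 11.4 CPM and the pseudoreceptor BAMBI at 208 and 110 CPM. Among immediate early and MAPK feedback genes (26 measured, percentile 75.4), the phosphatase DUSP2 was at 46.8 and 94.3 CPM, NR4A1 at 18.1 and 28.6 CPM, JUN at 102 and 57.8 CPM and DUSP1 at 16.2 and 10.7 CPM. Apoptosis regulators (26 measured, percentile 29.8) had the BH3-only genes PMAIP1 at 12.3 and 6.65 CPM, BMF at 28.3 and 16.9 CPM and BIK at 19.2 and 30.7 CPM, and CASP10 at 3.17 and 4.72 CPM.

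The other stress and metabolic lists did not stand apart. ATF4 response genes (28 measured, percentile 74.3) had the cytokine GDF15 at 69.8 and 141 CPM, CHAC1 at 17.8 and 9.81 CPM, VLDLR at 15.1 and 22.7 CPM and FGF21 at 1.02 and 1.98 CPM. Endoplasmic reticulum chaperones (26 measured, percentile 86.9) had HERPUD1 at 70.7 and 112 CPM, CREB3L2 at 74.0 and 51.4 CPM, PDIA3 at 741 and 1003 CPM and CALR at 1388 and 1813 CPM. Of 31 genes of fatty acid synthesis and oxidation (percentile 82.0), PPARA was at 18.1 and 33.7 CPM, the lipogenic regulator SREBF1 at 444 and 705 CPM, CPT1B at 17.1 and 9.29 CPM and EHHADH at a log2 change of 0.46. Cholesterol synthesis genes (25 measured, percentile 41.9) and nuclear-encoded respiratory chain genes (43 measured, percentile 41.0) had 0 members past 1.5-fold. Autophagy and lysosome genes also had 0 members past it (37 measured, percentile 89.9), with the endosomal adaptor gene WDFY1 at 38.0 and 45.3 CPM, TFEB at 12.0 and 17.1 CPM and ATG13 at 89.1 and 65.0 CPM. Cancer-testis antigens (12 measured, percentile 33.9) had SSX2, whose copies share reads, at 3.65 and 1.23 CPM.

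Few markers of other cell types reached a mean of 1 CPM. Fibroblast markers (8 measured, median -0.20, percentile 3.83) had FBN1 at 3.94 and 1.75 CPM, BGN at 5.99 and 10.9 CPM, COL6A1 at 174 and 124 CPM and COL1A1 at 41.5 and 32.5 CPM. Of endothelial markers 3 were measured, ESAM at 0.779 and 1.75 CPM, EGFL7 at 19.6 and 28.0 CPM and VWF at 3.75 and 3.40 CPM, and of leukocyte markers 2, CD68 at 6.67 and 9.95 CPM and CORO1A at 25.4 and 34.7 CPM. Of the reads on genes, 0.664% in the control and 0.658% in the knockdown fell on ribosomal RNA symbols.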

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

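Alternatives chosen after seeing the data were the exact test on reads, the removal of pseudogene, readthrough, antisense and similar models, the removal of the GC and length trend, and androgen receptor targets without KLK2, KLK3, KLK4 and NDRG1. With 1 library per group no library could be left out, and no paired analysis was possible because each group holds 1 library and the values come from no test. Of 950 values of the other named genes under other pseudocounts and scalings, 125 left their counting interval. Changes of sign were counted only for genes whose main change was at least 1.5-fold, and 0 were found. The log2 change of NRP2 was -1.08 with a pseudocount of 0.25 CPM. The numbers of genes at least 2-fold higher and lower were 320 and 136 with that pseudocount, 47 and 20 with one of 5 CPM, 101 and 44 at a mean of at least 5 CPM, and 769 and 476 at 1.5-fold. The direction of these shifts follows by construction. A smaller pseudocount or a lower threshold can only add genes, and a larger pseudocount or a stricter filter can only remove them. The other alternatives kept both numbers within 1.5 times.

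Of 11 lists that stood apart, 6 did so under all 11 alternatives: hypoxia and glycolysis, antigen presentation, VEGF and semaphorin genes, p53 targets, NRF2 targets and mitotic genes. In 11 of the 122 values of these 11 lists the position was lost. Without a filter on low values the Notch list stood at percentile 90.7 and androgen receptor targets at 94.63; without KLK2, KLK3, KLK4 and NDRG1 the latter stood at 90.92. By list mean, Notch stood at 95.28, integrins at 96.42 and ribosomal proteins at 89.91. Under quantile normalization, androgen receptor targets stood at 95.32 and ribosomal proteins at 55.76. Heat shock chaperones stood at 5.54 with equal library totals, 3.14 with a pseudocount of 5 CPM and 23.18 against unmatched random lists. In 12 of 286 values, other lists stood apart. Type I interferon genes stood at 97.89 with equal library totals, 98.9 at a mean of at least 5 CPM, 98.94 without a filter and 97.8 under quantile normalization. Quantile normalization also placed axon guidance at 98.16, luminal markers at 98.17 and fibroblast markers at 2.23. Luminal markers stood at 97.69 against unmatched lists, fibroblast markers at 1.78 with a pseudocount of 0.25 CPM, neuroendocrine markers at 97.78 with the 5 members left at a mean of at least 5 CPM, TGF-beta genes at 99.11 by list mean, and NF-kB genes at percentile 1 without a filter on low values. Apart from the members removed or added by a filter, the cause was not tested. Depth limits genes near the floor of 3 reads, 0.146 CPM in the control and 0.141 CPM in the knockdown, which include CHGA and INSM1.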

Other observations

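The genes in this paragraph, most of them next in rank after the named ones, were chosen after their values were seen. Higher in the knockdown library were STC1, a secreted hormone induced by hypoxia, at 13.7 and 44.8 CPM, the collagen prolyl hydroxylase P4HA1 at 84.8 and 228 CPM, and the pyruvate dehydrogenase kinase PDK1 at 44.8 and 118 CPM. The hypoxia and glycolysis list already counts P4HA1 and PDK1. RAB31, a small GTPase of vesicle transport, was at 8.03 and 30.1 CPM, and the secreted phospholipase PLA2G2A at 9.74 and 30.1 CPM. SRRM3, a splicing regulator of neuronal microexons, was at 3.60 and 10.9 CPM, while its relative SRRM4 had 0 and 1 read. Lower were the tubulin gene TUBA1A at 101 and 42.8 CPM, the Wnt cofactor BCL9 at 70.5 and 32.6 CPM, the corepressor TLE1 at 41.7 and 17.4 CPM and the ciliary receptor GPR161 at 44.4 and 18.3 CPM. REST, the repressor of neuronal genes, was at 76.9 and 73.1 CPM.

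Several tests below were chosen only after the results were seen: the removal of the GC and length trend, the split of the hypoxia list, the androgen receptor list without KLK2, KLK3, KLK4 and NDRG1, the androgen-repressed genes, and the sums over HLA genes. Hypoxia and glycolysis genes were higher together. A trend with GC content and transcript length is argued against as the whole cause, since the list's median was 0.72 both before and after its removal. The increase was not limited to glycolytic enzymes in these 2 libraries. The 12 measured members outside glycolysis had a median of 0.84, with 7 at least 1.5-fold higher and 0 lower. That split is no independent test, since 30 of the list's 31 measured members had already been seen above 0. Members outside glycolysis that stayed under 1.5-fold included ANKRD37 at 2.48 and 2.31 CPM, EGLN3 at 14.2 and 17.5 CPM and CA12 at 137 and 164 CPM. These genes were chosen after their values were seen. A candidate explanation is a stronger response to low oxygen. It could come from silencing itself, or from culture density, medium or oxygen that may have differed between the cultures. With 1 library per group these stay open and were not tested.

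Androgen receptor targets stood apart on the high side, with 9 of 30 members at least 1.5-fold higher, but no longer did so without a filter on low values (percentile 94.63) or under quantile normalization (percentile 95.32, median 0.08). Removing the GC and length trend left the median of the 28 members with a value at 0.16, against 0.14 before, and the list still apart. Whether KLK2, KLK3, KLK4 and NDRG1 alone set the position stays open: without them the list stood at percentile 90.9, but taking out high members lowers any list, and 5 of the other 26 members were at least 1.5-fold higher and 0 lower. Higher output of the receptor overall may lower the genes it represses, and the 10 measured genes of an androgen-repressed list had a median of -0.24 at percentile 0.57, but that list was written after OPRK1 and the UGT2B genes had been seen and 5 of its members lay above 0, with 1 at least 1.5-fold higher and 4 lower. The test was then limited to the 4 measured members not seen before, whose median was 0.24, too few to decide, so this stays open, as does silencing itself.

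Antigen presentation genes were higher. A GC and length trend is argued against as the whole cause, since its removal left the median at 0.43, against 0.49. Reads moved among HLA genes are argued against, since the summed level of all 25 HLA genes listed was 1.58-fold higher (1.54 to 1.63), 471 and 747 CPM. The 11 measured members outside the HLA genes had a median of 0.24 at percentile 97.3, just short of standing apart. Silencing itself or a difference between the cultures may account for the pattern, and neither was tested.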
